A study of Arabidopsis thaliana with 9 samples.

How the data were processed

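Leaf RNA of 3 Arabidopsis thaliana genotypes was measured on 9 Affymetrix arrays, 3 per genotype. Per the labels' protocols, each array held RNA from its own biological replicate, for which leaves of 8 or more plants in the Col-0 background were combined, harvested after 3 weeks at 200 umol m-2 s-1, 16 h light and 65% humidity, and biotin-labelled cRNA was made from 5 ug of total RNA. No wild-type array was analysed here, so every value is relative to a genotype that lacks the catalase CAT2. The genotypes are named here as in the labels' genotype field; the sample titles call the lines cat2-2, cat2-2 atrbohD and cat2-2 atrbohF.

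The deposited values are log2 expression values per probe set, which the authors made with GCRMA, per the submitters' processing notes; its version is not given in the sources used here. GCRMA corrects the background from probe sequence, normalizes the arrays to each other by quantiles and summarises the probes of each set. Such normalization sets the distribution of every array nearly equal, so a change shared by most transcripts would not be seen. The medians of the 9 arrays lay between 6.05 and 6.12.

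The table held 22810 probe sets, of which 64 control probe sets were left out. A probe set was kept where its third-highest value of the 9 arrays exceeded 5.14, the 40th percentile of all values, which left 13888. Arrays have no read depth, and the number of arrays limits the precision. The median standard error of a log2 fold change was 0.10.

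Each comparison was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no trend), with 1 mean per genotype and 1 spread estimated from all 9 arrays (6 residual degrees of freedom). P-values were adjusted by Benjamini-Hochberg within each comparison, and a probe set was called changed at an adjusted p under 0.05. The probe annotation gave 1 gene for 13513 probe sets and several for 503, and did not list 8730; symbols were updated through a RefSeq gene table of the TAIR10.1 assembly, used only for names, which matched 13436. A probe set it does not list is unnamed here, not without a gene. Of the 13888 tested probe sets, 7435 had 1 gene.

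The probe sets of RBOHD, RBOHF and CAT2 were not named by the annotation used here, so the transcripts of the mutated genes could not be picked out by name. The genotype labels were not checked by named probe sets of these genes. Lists of pathway genes and cell type markers were fixed by locus code before the data were examined (31 lists, 423 loci). Only 67 of these loci had a probe set with 1 gene and 58 were tested, so counts below refer to the few members that could be named. No member was tested for the lists of NADPH oxidases and catalases, camalexin and tryptophan, indole glucosinolates, phosphate starvation, and the markers of flowers, vasculature, epidermis and dividing cells. The 10 lists with at least 3 tested genes were tested with limma's camera at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, which asks whether the genes of a set move one way and does not compare the set with other genes. No camera call held after adjustment with an estimated correlation. For each gene the probe set with the highest mean was used.

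Named genes follow a rule fixed before the data were examined. It takes per comparison the 8 largest rises and the 8 largest falls among called probe sets of 1 gene whose groups do not overlap, and up to 4 called members of each list, or up to 2 with the smallest p where none was called. Families of at least 8 genes sharing a symbol stem, and the plastid-encoded genes, were added as lists after the data were seen, 17 in all.

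Both comparisons against cat2 use the same 3 cat2 arrays, which makes their fold changes correlate without any effect. Unchanged groups were therefore simulated 100 times, with each probe set's residual SD. Arrays were drawn independently with the same SD in each genotype, so no pairing by replicate number was simulated. The fit was tested on simulated data of 13888 probe sets, with known changes in 67 of them at 0.5, 67 at 1 and 66 at 2 on the log2 scale in each comparison, so the shares below rest on few changed probe sets. For cat2 rbohD against cat2 it recovered 53.7% of changes of 0.5 on the log2 scale and 98.5% of changes of 1; for cat2 rbohF against cat2 the shares were 59.7% and 97.0%, and for cat2 rbohF against cat2 rbohD 68.7% and 98.5%. False calls made up 4.55%, 7.07% and 7.29% of the calls in these comparisons. All genotypes were simulated with the same spread, whereas the measured cat2 rbohD arrays varied most. Recovery in the comparisons with cat2 rbohD may therefore be lower than these shares.

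The alternatives tried were 3 other filters on dim probe sets, quantile normalization again, centring each array on its median, an intensity trend, robust eBayes, array weights, only the 6 arrays compared, the replicate number as a block, and leaving out each array in turn. Weights per genotype were added after the data were seen, because the cat2 rbohD arrays varied more. Arrays of 1 genotype held identical values at only 1.67% to 2.10% of probe sets, so all 9 were counted as separate replicates. The labels give the replicates of each genotype the same numbers without saying what a number marks. For cat2 and cat2 rbohF the data gave a weak sign of pairing. Deviations from the group means correlated at 0.142 to 0.171 in the 3 same-numbered pairs and at -0.197 to 0.0412 in the others. Deviations within 3 arrays depend on each other, so such a pattern can arise without a pairing. Values from the fit with the replicate block are therefore given beside results of that comparison whose call they change.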

Results

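The 9 arrays measured leaf transcripts of cat2, cat2 rbohD and cat2 rbohF plants, 3 pools of plants each. CAT2 is the main leaf catalase, which removes hydrogen peroxide made in photorespiration, so that cat2 leaves are under oxidative stress from inside the cell at the light level used. RBOHD and RBOHF are plasma membrane NADPH oxidases that make superoxide in the apoplast. The design asks how the transcript profile of cat2 leaves changes when either oxidase is also missing, and whether both losses act alike.

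The genotypes separated on the first principal component, which held 49.0% of the variance. Its scores ran from -24.4 to -15.1 in cat2 and from 14.4 to 26.2 in cat2 rbohF. The cat2 rbohD arrays scored -10.1, -10.7 and 10.4, so that replicate 3 lay toward cat2 rbohF. Its values correlated at 0.983, 0.988 and 0.984 with cat2 rbohF replicates 1, 2 and 3, and at 0.977 and 0.983 with the other cat2 rbohD arrays. The cat2 rbohF arrays correlated at 0.991 to 0.994 with each other. The cat2 rbohD arrays also varied most, with a mean variance of 0.0502 on the log2 scale against 0.0285 in cat2 and 0.0212 in cat2 rbohF (n = 3 each).

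The comparison of cat2 rbohF with cat2 asks what the added loss of RBOHF changes. Of the few members measured, 3 of 4 salicylic acid genes and 3 of 3 oxidative stress markers fell in cat2 rbohF and 3 of 3 cold response genes rose. None of these lists passed as a set with an estimated correlation (limma camera adjusted p = 0.217 each). With fry, which does not compare a set with other genes, all 3 lists passed (fry adjusted p = 0.0103 each). WRKY53, a transcription factor of senescence and defence, fell 3.95-fold, and COR15A, a chloroplast protein gene induced by cold, rose 2.86-fold. In cat2 rbohF against cat2, 2273 of 13888 probe sets changed (limma adjusted p under 0.05), 899 higher and 1374 lower; with each array centred on its median these were 1137 and 1206. Of these, 324 changed at least 2-fold, 82 higher and 242 lower. The groups did not overlap at 38.7% of probe sets, where chance gives 10%.

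All 3 measured oxidative stress markers fell in cat2 rbohF. The log2 fold changes were -1.25 ± 0.26 (SE) for STZ, a zinc finger repressor also called ZAT10, -1.10 ± 0.23 for the glycosyltransferase gene UGT73B5 and -1.09 ± 0.32 for the glutathione transferase gene GSTU25. The GSTU25 mean in cat2 rbohF, 4.31, lay under the filter value of 5.14, where differences are compressed, so its size is uncertain. The list moved down as a set (limma camera adjusted p = 0.0103; adjusted p = 0.217 with an estimated correlation). Of the 4 measured genes of salicylic acid signalling and PR defence, 3 fell and 1 did not pass, SAG101. WRKY53 fell by 1.98, UGT76B1, whose product glucosylates salicylic acid, by 1.65 and the glutaredoxin gene GRX480 by 0.71 on the log2 scale (limma camera adjusted p = 0.00571; adjusted p = 0.217 with an estimated correlation). Adjusted over the list alone, 3 members fell in each of these lists. WRKY53 and GRX480 stayed called without any single array. STZ lost the call without cat2 replicate 2 (limma adjusted p = 0.0537), UGT73B5 without cat2 replicate 2 or cat2 rbohF replicate 1 or 3 (up to 0.0563), UGT76B1 without cat2 replicate 1 or 2 or cat2 rbohF replicate 1 or 3 (up to 0.118), and GSTU25 without cat2 replicate 1 or 2, cat2 rbohD replicate 2 or any 1 cat2 rbohF array (up to 0.145) or without a filter.

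Of 4 pattern-triggered immunity genes, WRKY6 (-1.02) and the receptor-associated kinase gene BIK1 (-0.43) fell and 2 did not pass; adjusted over the list alone, 3 fell. The set test gave a limma camera adjusted p of 0.00571, and an adjusted p of 0.217 with an estimated correlation. The fry adjusted p was 0.00354. Both measured endoplasmic reticulum folding genes fell, the unfolded protein response factor BZIP60 by 0.83 and the co-chaperone ATERDJ3B by 0.63. Of 3 heat shock genes, AT5G48570 (-2.15), an immunophilin gene, fell and 2 did not pass; adjusted over the list alone, all 3 fell (limma camera adjusted p = 0.0222; adjusted p = 0.315 with an estimated correlation). The heat shock set did not pass without cat2 replicate 1 or 2 or with the stricter filter (limma camera adjusted p up to 0.0568). On all arrays it passed with fry (fry adjusted p = 0.0422). BIK1 and AT5G48570 lost the call without cat2 replicate 2 or cat2 rbohF replicate 1 or 3 (limma adjusted p up to 0.0678 and 0.0602), and ATERDJ3B without cat2 rbohF replicate 1 (0.0628); WRKY6 and BZIP60 stayed called without any single array.

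The plant defensin genes PDF1.2 and PDF1.2b fell by 1.55 ± 0.34 and 1.87 ± 0.43 (SE), 2 of 4 measured jasmonate genes, and also 2 adjusted over the list alone. The list as a set did not pass (limma camera adjusted p = 0.133). Both probe sets ran alike over the arrays, at 9.18, 10.29 and 10.14 against 9.26, 10.42 and 10.24 in cat2 rbohD. They may therefore not be 2 separate signals. NDB2, an external NAD(P)H dehydrogenase of mitochondria, fell by 1.33, 1 of 2 measured mitochondrial retrograde markers. CCR2, a cinnamoyl-CoA reductase, fell by 1.21 ± 0.14 and GH3.3, an auxin-conjugating enzyme gene, by 1.16. Other large falls were AT1G76470 (-2.34), the receptor-like kinase gene B120 (-2.12, with a mean of 4.39 in cat2 rbohF, also under the filter value), the berberine bridge enzyme-like gene AT1G26380 (-1.91), AT3G02840 (-1.90) and AT4G19370 (-1.83, with a mean of 5.11 in cat2 rbohF, also under that value). PDF1.2 and PDF1.2b lost the call without cat2 replicate 2 or 3 (limma adjusted p up to 0.0553 and 0.0713), GH3.3 without cat2 replicate 1 or 3 or cat2 rbohF replicate 1 or 3 (up to 0.0778), and AT3G02840 without cat2 replicate 1 or 2 or cat2 rbohF replicate 1 or 3 (up to 0.0752).

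All 3 measured cold response genes rose in cat2 rbohF, COR15A by 1.52 ± 0.34, COR15B by 0.88 ± 0.13 and the dehydrin gene COR47 by 0.76 ± 0.21 on the log2 scale, and all 3 adjusted over the list alone (limma camera adjusted p = 0.00571; adjusted p = 0.217 with an estimated correlation). The dehydrin gene LTI30 rose by 1.61 and the sugar transporter gene SAG29 by 1.59, the only members measured of the abscisic acid and senescence lists. Of 4 anthocyanin pathway genes, DFR (1.27) and UF3GT (0.84) rose and 2 did not pass; 3 rose adjusted over the list alone (limma camera adjusted p = 0.0222; adjusted p = 0.315 with an estimated correlation). BCAT4, of methionine-derived glucosinolate synthesis, rose by 1.12 ± 0.17, the clock gene GI by 0.47 and PYK10, the beta-glucosidase gene fixed as a root marker, by 1.35. The largest rises of named genes were AT4G17470 (3.21), AT5G62360 (1.92) and AT2G39920 (1.63). The control signal of GAPDH at 3' over 5' probe sets, a measure of RNA quality, was 0.75 ± 0.06 in cat2 and 0.91 ± 0.07 in cat2 rbohF (log2, SD, n = 3), while those of actin (2.60 and 2.47) and ubiquitin (1.33 and 1.29) were lower in cat2 rbohF by less than the SD in cat2. Another pair of GAPDH control sets went the other way, with log2 fold changes of -0.31 at its 3' set and -0.11 at its 5' set. The root marker PYK10 rose with the genes named above.

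COR15B, BCAT4, PYK10 and the 3 largest rises stayed called without any single array. COR15A lost the call without cat2 replicate 1 or cat2 rbohF replicate 1 or 3 (limma adjusted p up to 0.077), COR47 and SAG29 without any 1 cat2 array or cat2 rbohF replicate 1 or 3 (up to 0.14 and 0.113), UF3GT without cat2 replicate 1 or 2 or cat2 rbohF replicate 1 or 3 (up to 0.127), and GI without cat2 replicate 2 or cat2 rbohF replicate 1 (up to 0.0607). COR47 and UF3GT also lost it without a filter, and LTI30 and DFR without a filter, with robust eBayes or with only the 6 arrays compared. LTI30 lost it without cat2 replicate 1 or 3, cat2 rbohD replicate 1 or 2, or cat2 rbohF replicate 1 or 3 (up to 0.16), and also with the replicate block (limma adjusted p = 0.0726), and DFR without cat2 replicate 1 or 2, cat2 rbohD replicate 1 or 2, or any 1 cat2 rbohF array (up to 0.152). The anthocyanin set did not pass without cat2 rbohF replicate 3 or with the stricter filter (limma camera adjusted p up to 0.115). With fry it did not pass either (fry adjusted p = 0.0608).

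Antioxidant recycling genes moved both ways. Of 5 measured ascorbate-glutathione enzymes, the thylakoid ascorbate peroxidase gene TAPX rose by 0.42, GR1 (-0.36) and ATMDAR2 (-0.54) fell, and 2 did not pass, with the same counts adjusted over the list alone. Their median was 0.06 while the mean was -0.05 and the test pointed down (limma camera adjusted p = 0.817). ATMDAR2 lost the call without cat2 replicate 2 or 3 or cat2 rbohF replicate 1 or 3 (limma adjusted p up to 0.0835). Of 5 photorespiration genes, AT1G32470 rose (0.27), also adjusted over the list alone, and 4 did not pass; the set moved up with a median of 0.24 (limma camera adjusted p = 0.0169; adjusted p = 0.261 with an estimated correlation). AT1G32470 lost the call without cat2 replicate 2 or 3, cat2 rbohD replicate 1 or 2, or any 1 cat2 rbohF array (limma adjusted p up to 0.15), without a filter, with only the 6 arrays compared and with the replicate block (limma adjusted p = 0.0596). None of 5 photosynthesis genes passed, and their set did not either (limma camera adjusted p = 0.259). All 5 were positive, however, and the set passed with fry, as did the photorespiration set (fry adjusted p = 0.0135 each). EIN3, APS3, PYE and the guard cell marker FMA, each the only gene tested of its list, had log2 fold changes of -0.15, 0.11, -0.18 and 0.15 and did not pass.

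The count for cat2 rbohF moved over 1.5 times with single arrays, to 817 without cat2 rbohF replicate 1, 1099 without cat2 rbohF replicate 3, 1080 without cat2 replicate 2 and 1404 without cat2 replicate 3. The 2-fold count was 198 without cat2 rbohF replicate 1.

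**Figure D1:**
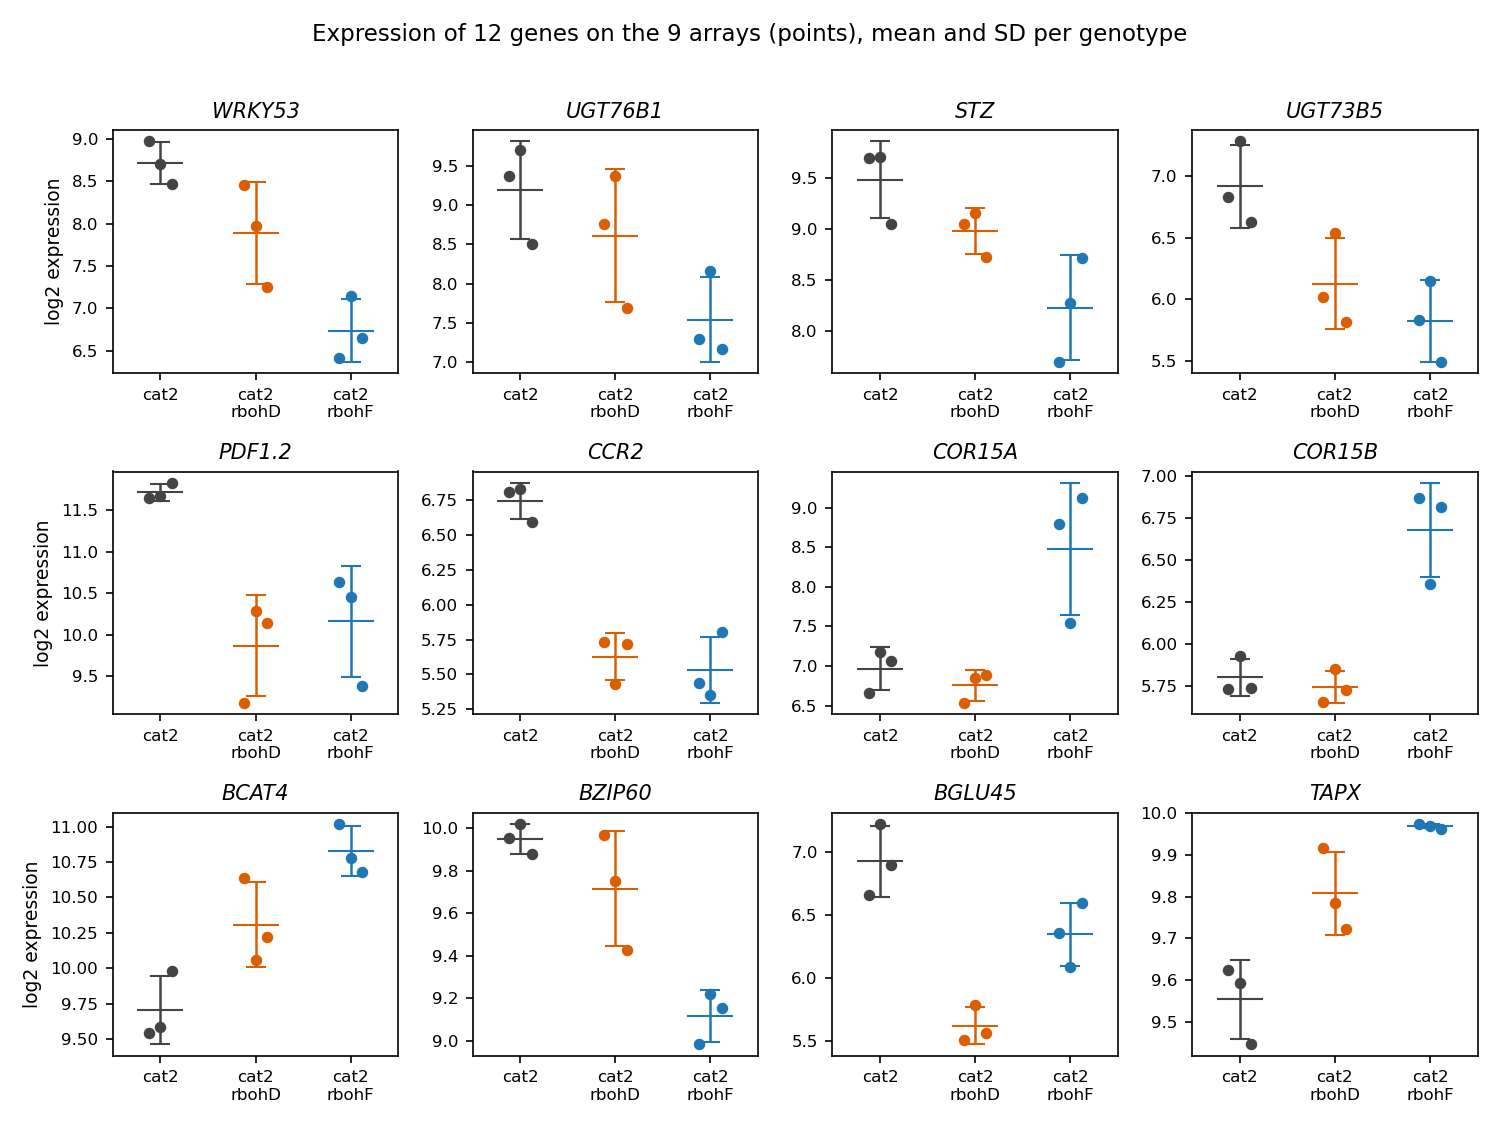
Log2 expression (vertical axes, each with its own range) of 12 genes on the 9 arrays by genotype (horizontal axes), with points for arrays and bars for mean and SD of 3 arrays. COR15A lay between 7.54 and 9.12 in cat2 rbohF, above its values of 6.53 to 7.18 in the other arrays, and CCR2 lay lower in both double mutants than in cat2.

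The comparison of cat2 rbohD with cat2 asks the same of RBOHD. Few transcripts passed the threshold, and most of these fell. In cat2 rbohD against cat2, 29 probe sets changed (limma adjusted p under 0.05), 3 higher and 26 lower, and 13 fell at least 2-fold. The cinnamoyl-CoA reductase gene CCR2 fell by 1.12 ± 0.14 (SE) on the log2 scale and BGLU45, whose product acts on monolignol glucosides, 2.46-fold, and AT1G76470 fell by 1.36. The other named calls were AT4G19370 (-0.94), AT5G55420 (-0.92) and AT4G39230 (-0.75), which fell, and AT4G32340 (0.84), AT4G30660 (0.84) and AT2G40960 (0.80), which rose.

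An unnamed probe set fell to 4.44 in cat2 rbohD from 9.58 in cat2, and was at 8.94 in cat2 rbohF. Its log2 fold change was -5.15 ± 0.08 (SE) against cat2 (limma adjusted p = 1.05e-09), a size left uncertain because the cat2 rbohD mean lies under the filter value of 5.14. Of the named genes followed here, those nearest to it by probe set number were AT5G48570 and AT5G44420. The locus of RBOHD lies between them by locus code. The probe set may therefore read RBOHD itself, which was not checked. Another unnamed one, at 8.78 in cat2, fell by 2.86 in both double mutants.

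No list member other than CCR2, 1 of 2 measured phenylpropanoid genes, passed in cat2 rbohD. PDF1.2 and PDF1.2b had log2 fold changes of -1.84 and -1.92 with limma adjusted p = 0.091 and 0.147, and both passed when adjusted over the list alone. The jasmonate list rested on this pair, since OPCL1 was at -0.07 and 1 of the 4 measured members was positive. GH3.3 was at -1.22 (limma adjusted p = 0.147). The sets of jasmonate, oxidative stress, pattern-triggered immunity and anthocyanin genes passed (limma camera adjusted p = 0.018 each), as did salicylic acid (0.0239); none passed with an estimated correlation (adjusted p = 0.324, 0.324, 0.324, 0.353 and 0.353). Their medians were -0.96, -0.54, -0.21, 0.62 and -0.43, and adjusted over the list alone 2, 1, 2, 0 and 2 members passed. With fry none of these sets passed (fry adjusted p = 0.175, 0.175, 0.0636, 0.241 and 0.241). The 3' over 5' signal of GAPDH was 0.86 ± 0.08 in cat2 rbohD (SD, n = 3), without overlap with cat2, where it was 0.75 ± 0.06. Those of actin and ubiquitin were 2.56 and 1.25, against 2.60 and 1.33 in cat2. The other pair of GAPDH control sets went the other way, with log2 fold changes of -0.04 at its 3' set and 0.06 at its 5' set. The jasmonate set did not pass without cat2 replicate 3 or cat2 rbohD replicate 1 (limma camera adjusted p up to 0.09), the oxidative stress set without cat2 replicate 2 or cat2 rbohD replicate 3 (up to 0.139), and the immunity set without cat2 replicate 2 (0.106). The anthocyanin set did not without cat2 replicate 2 or cat2 rbohD replicate 2 or with the stricter filter (up to 0.139), nor the salicylic acid set without cat2 replicate 1 or 2 or cat2 rbohD replicate 3 (up to 0.323). The other 5 sets did not pass, namely ascorbate-glutathione, cold response, heat shock, photorespiration and photosynthesis (limma camera adjusted p = 0.428, 0.982, 0.203, 0.142 and 0.428); the cold response median was -0.06 with the camera direction up and the fry direction down.

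Of the 13888 probe sets, 1499 had an unadjusted limma p under 0.05, a count that chance alone fills in part. The groups did not overlap at 13.4%, where chance gives 10%. The count of 29 changed probe sets fell to 7 without cat2 replicate 2, to 7 without cat2 replicate 3 and to 7 without cat2 rbohD replicate 1. It was 12 with the stricter filter, 18 with array weights and 15 with only the 6 arrays compared. The 2-fold count was 5, 6 and 6 without those 3 arrays. AT1G76470 and both unnamed probe sets described stayed called without any single array. CCR2 and AT4G19370 lost the call without any 1 cat2 array or cat2 rbohD replicate 1 (limma adjusted p up to 0.0886 and 0.0862), BGLU45 without cat2 replicate 2 or 3 or cat2 rbohD replicate 1 (up to 0.0866), and AT4G32340 without cat2 replicate 1 or 2 or cat2 rbohD replicate 1 (up to 0.0936) or with only the 6 arrays compared. AT5G55420, AT4G39230, AT4G30660 and AT2G40960 each lost it with any 1 array left out (up to 0.158, 0.191, 0.136 and 0.16) except cat2 rbohF replicate 1 or 2 for AT5G55420, cat2 rbohD replicate 2 or 3 for AT4G39230, cat2 rbohD replicate 2 or cat2 rbohF replicate 2 for AT4G30660, and cat2 replicate 1 or cat2 rbohD replicate 3 for AT2G40960. Each of these 4 also lost it with array weights and with genotype weights, and under 1 or more other alternatives with all arrays.

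The double mutants were then compared directly, which tests whether both losses differ in effect. Against cat2 rbohD, the cold-regulated COR15A rose by 1.73 ± 0.34 and COR15B by 0.93 ± 0.13 (SE) in cat2 rbohF, and the list moved up as a set (limma camera adjusted p = 0.00258; adjusted p = 0.408 with an estimated correlation), with COR47 at 0.56 not passing and all 3 passing adjusted over the list alone. AT4G33150, of lysine breakdown, rose by 1.61, AT3G28220 by 1.70, AT1G62510 by 1.61 and AT5G62360 by 1.43. SAL2 fell by 1.54, AT5G66890 (whose mean of 5.00 in cat2 rbohF lay under the filter value, so that its size is uncertain) and AT1G72240 by 1.24 each, RING1, a ubiquitin ligase gene of pathogen response, by 1.06 and NDB2 by 0.93.

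In all, 267 probe sets differed (limma adjusted p under 0.05), 120 higher and 147 lower in cat2 rbohF; with each array centred on its median these were 148 and 118. Of the 267, 247 had the larger absolute change against cat2 in cat2 rbohF. The 4 salicylic acid genes moved down as a set (limma camera adjusted p = 0.0191; adjusted p = 0.408 with an estimated correlation), though no member passed over all probe sets and 2 fell adjusted over the list alone, and WRKY53 was at -1.16 (limma adjusted p = 0.0646). No set passed for heat shock, pattern-triggered immunity, photorespiration (limma camera adjusted p = 0.0897 each), oxidative stress (0.099), anthocyanins (0.398), photosynthesis (0.568), jasmonate (0.669) or ascorbate-glutathione genes (0.767). PDF1.2 and CCR2 were at 0.29 ± 0.34 and -0.10 ± 0.14 (SE) and did not pass.

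This count rested on single arrays and on the shared spread. It was 39, 107 and 74 without cat2 replicates 1, 2 and 3, 4, 3 and 1065 without cat2 rbohD replicates 1, 2 and 3, 1 and 8 without cat2 rbohF replicates 1 and 3, and 2 with only the 6 arrays compared; each gene named as changed between the double mutants lost the call without cat2 rbohD replicate 1, cat2 rbohD replicate 2 or cat2 rbohF replicate 1 and with only the 6 arrays compared (limma adjusted p up to 0.199 over all alternatives). The salicylic acid set did not pass without cat2 rbohD replicate 2 (limma camera adjusted p = 0.172). With fry it did not pass either (fry adjusted p = 0.0898), while the cold response set did (fry adjusted p = 0.0374).

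All 29 probe sets changed in cat2 rbohD were also changed in the same direction in cat2 rbohF, 3 higher and 26 lower. They include the unnamed probe set that may read RBOHD itself. Independent lists of these sizes would share 0.194 and 2.57, a reckoning that leaves out the shared cat2 arrays. Simulated unchanged groups, in which few calls arise, shared 0, and neither number is the overlap to be had from shared arrays alone at these list sizes. Over all probe sets, 69.9% had the same sign in both comparisons, against 66.6% in simulated unchanged groups. Across probe sets, which are not independent replicates, the log2 fold changes correlated with Pearson's r = 0.672 (Spearman's rho = 0.575), against 0.499 (0.461) in simulated unchanged groups that share the cat2 arrays. The covariance was 0.0503 against a simulated 0.0111, a difference of 0.0392. The 3 cat2 arrays do not divide into 2 sets of at least 2 arrays, and no split was tried, so part of the excess may come from the shared arrays. Without cat2 rbohD replicate 3, r was 0.474. Unchanged groups were not simulated with an array left out, so 0.499 is not the value to set beside it.

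**Figure D2:**
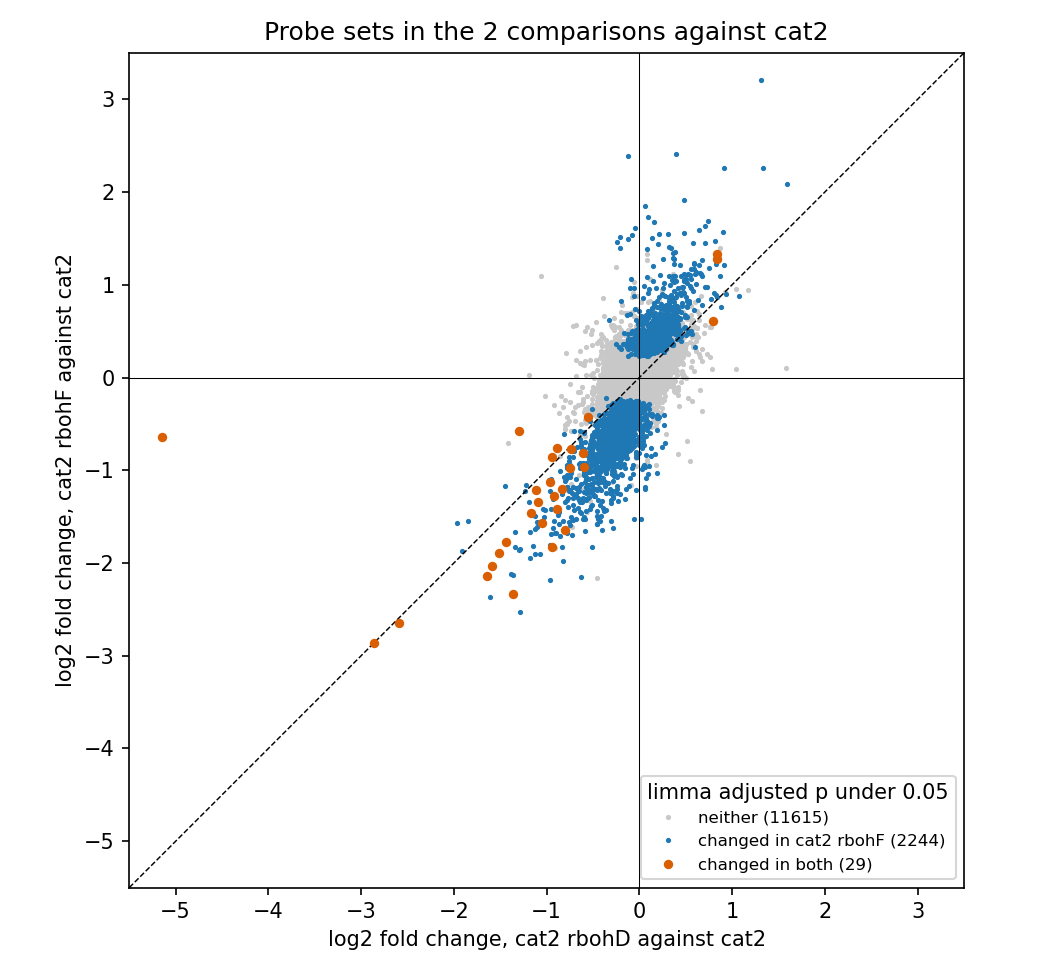
Log2 fold change against cat2 of each tested probe set in cat2 rbohD (horizontal axis) and in cat2 rbohF (vertical axis), coloured by limma adjusted p under 0.05, with a dashed line of equal change. The 29 probe sets changed in both lie at the lower left and upper right, and 1 unnamed probe set stands apart at -5.15 on the horizontal axis.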

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

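The tests of array spread, of probe sets that differ between the double mutants and of a smaller version of the same change were chosen after the results were seen, as was the count adjusted over 29 probe sets alone; the tests of a misplaced array and of other splits were written before.

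The effects of the 2 oxidase losses against cat2 differed by a direct test at 267 probe sets, though at 1 without cat2 rbohF replicate 1 and at 1065 without cat2 rbohD replicate 3, with all other such counts between them. The array cat2 rbohD replicate 3 correlated at 0.983 to 0.988 with cat2 rbohF and at 0.977 and 0.983 with its own genotype. The cat2 rbohF arrays correlated more highly with each other, at 0.991 to 0.994. These values do not by themselves make cat2 rbohD replicate 3 a mislabelled cat2 rbohF array. At the unnamed probe set that fell in cat2 rbohD, this array also lay with the others of its genotype (mean 4.44). It did not lie with cat2 rbohF there (mean 8.94), which argues against such a label error, on 1 probe set. Why the array lay toward cat2 rbohF was not tested. The count of 267 still depends on it, as does the agreement of both comparisons against cat2, which was 0.474 without it. The cold response genes lay 0.93 higher (median log2 difference, 3 genes) and the salicylic acid and PR defence genes lay 0.75 lower (median -0.75, 4 genes) in cat2 rbohF than in cat2 rbohD, by limma camera with a preset correlation; neither set passed with an estimated correlation (adjusted p = 0.408 each), nor the salicylic acid set without cat2 rbohD replicate 2 (limma camera adjusted p = 0.172).

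More probe sets changed in cat2 rbohF than in cat2 rbohD, 2273 against 29. A single misplaced cat2 rbohD array is argued against, since the highest count with 1 such array left out was 31, while the lowest for cat2 rbohF with any array left out was 817. Larger spread of the cat2 rbohD arrays around effects of equal size is argued against as well. The SD of log2 fold changes, corrected for the noise of each genotype, was 2.39 times as large in cat2 rbohF, and at least 2.15 times with any array left out. A larger effect of losing RBOHF is consistent with these values, as a hypothesis, while a difference between the plant lines outside the mutated genes stays open and untested.

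Probe sets changed in cat2 rbohD were changed in the same direction in cat2 rbohF. One technical reading is that the cat2 arrays or the cat2 line lie apart from both double mutants alike. At 6 of the 29 probe sets the double mutants differed from each other (limma adjusted p under 0.05), though at 1 to 7 with an array left out. Adjusted over the 29 alone, 11 differed, of which 9 lay further from cat2 in cat2 rbohF. At least 8 did so with any array left out, so an equal shift alone does not account for all 29. Such a shift with a further change in cat2 rbohF on top would give the same values. Of the other 23, 18 had no difference by either count. For all 29, a shift of cat2 and a shared effect of both oxidases cannot be told apart, because no second set of cat2 plants was analysed here.

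Each comparison of 3 against 3 arrays allows 10 splits, too few for a share under 0.05. The real split gave 29, 2273 and 267 changed probe sets, 1 of 10 splits reached that number in each comparison, and the highest other split gave 0. The other splits mix both genotypes, which puts any real difference into the spread. A count of 0 there therefore does not bear on whether the calls are sound.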

How the results depend on the processing

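Weights per genotype were the 1 alternative chosen after the data were seen. The count for cat2 rbohF against cat2 stayed within 1.5 times of 2273 under all alternatives except leaving out an array (817 to 2704). The count for cat2 rbohD against cat2 (29) was 12 with the 60th percentile filter, 18 with array weights, 15 with only the 6 arrays compared, 54 with the replicate block, 18 with genotype weights, and 7 to 35 with an array left out. The count for cat2 rbohF against cat2 rbohD (267) was 164 without a filter, 455 with the 60th percentile filter, 703 with array weights, 2 with only the 6 arrays compared, 127 with genotype weights, and 1 to 1065 with an array left out. Fewer arrays lower the degrees of freedom; the cause was not tested otherwise. The correlation of the 2 comparisons against cat2 (0.672) ranged from 0.474 to 0.713 with an array left out and moved by less than 1 SD of those values (0.0725) otherwise.

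The replicate numbers paired neither cat2 with cat2 rbohD (1 of 3 same-numbered correlations of deviations over 0.1, from -0.235 to 0.157) nor the double mutants (2 of 3, from -0.113 to 0.25). With the replicate block the counts were 54, 2300 and 393, and for cat2 rbohF against cat2 it shared 2034 of the 2273 and changed the call of no other named gene or list than those printed beside their results. In the other 2 comparisons 3 called probe sets of those followed lost the call, BGLU44 and BGLU15 (limma adjusted p = 0.0505 and 0.0536) among them, and 6 gained it. Between the double mutants the heat shock, oxidative stress and VPS sets then passed (limma camera adjusted p = 0.00554, 0.0282 and 0.037), as did heat shock for cat2 rbohD against cat2 (0.0173). None did with an estimated correlation (adjusted p = 0.247, 0.247, 0.539 and 0.276). No named gene or gene list reversed. Of 94 called values of named genes, 38 lost the call under at least 1 alternative with all arrays or the 6 compared, and 60 with an array left out; of 17 called list tests these were 3 and 9. Probe sets near the filter value of 5.14 have little signal over background, which compresses their fold changes.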

Other observations

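The hypothesis test below was chosen after the results were seen, as were the gene families.

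Some sugar transporter and beta-glucosidase genes, grouped by symbol after the data were seen, changed in cat2 rbohF. Of 8 measured SWEET genes, 3 rose in cat2 rbohF against cat2, SAG29 (1.59), the vacuolar fructose transporter gene SWEET17 (0.63) and SWEET16 (0.92), and 5 did not pass; the family did not pass as a set (limma camera adjusted p = 0.0691). SWEET17 stayed called without any single array. SAG29 lost the call without any 1 cat2 array or cat2 rbohF replicate 1 or 3 (limma adjusted p up to 0.113), and SWEET16 without any 1 cat2 or cat2 rbohF array (up to 0.0915). Of 10 BGLU genes, PYK10 (1.35), BGLU44 (0.97) and BGLU15 (0.72, from a cat2 mean of 4.79, under the filter value of 5.14, so that its size is uncertain) rose and BGLU45 (-0.58) fell, and 6 did not pass (limma camera adjusted p = 0.0691). BGLU45 lost the call without cat2 replicate 2 or 3 or cat2 rbohF replicate 1 or 2 (limma adjusted p up to 0.127), without a filter, and with the replicate block (limma adjusted p = 0.0523). Between the double mutants, BGLU44 (0.79) and BGLU15 (0.63) were higher in cat2 rbohF, and the family moved up as a set (limma camera adjusted p = 0.000756; adjusted p = 0.381 with an estimated correlation). The family passed with fry (fry adjusted p = 0.037). Both genes lost the call without any 1 cat2 array, cat2 rbohD replicate 1 or 2, or cat2 rbohF replicate 1 or 3 (limma adjusted p up to 0.177), and BGLU15 also without cat2 rbohF replicate 2. Both also lost it with only the 6 arrays compared or with genotype weights, and BGLU15 without a filter.

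Of the 17 added lists, the 64 plastid-encoded genes also moved up as a set between the double mutants (54 positive, median 0.21, limma camera adjusted p = 0.000855; adjusted p = 0.711 with an estimated correlation). So did the 8 genes of the RPS symbol family, most of them plastid-encoded too (8 positive, median 0.31, limma camera adjusted p = 0.0018; adjusted p = 0.466 with an estimated correlation). No member of either passed over all probe sets, and neither set passed with fry (fry adjusted p = 0.377 and 0.104). The plastid-encoded set did not pass without cat2 rbohD replicate 3 or cat2 rbohF replicate 1 (limma camera adjusted p up to 0.21). Against cat2 it did not pass in cat2 rbohF (limma camera adjusted p = 0.0649; adjusted p = 0.759 with an estimated correlation) but did with the replicate block (0.0109; adjusted p = 0.638 with an estimated correlation), without a filter, with the stricter filter, and without cat2 replicate 2 or cat2 rbohF replicate 2 or 3.

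BGLU45 was 2.46-fold lower in cat2 rbohD and 1.49-fold lower in cat2 rbohF than in cat2, and the difference between the double mutants did not pass (0.72, limma adjusted p = 0.0537). Of 19 Arabidopsis control probe sets, 1, a 3' GAPDH set, was lower in cat2 rbohF than in cat2 (-0.31, limma adjusted p = 0.0335) and 0 in cat2 rbohD. The 3' over 5' signal of GAPDH was 0.75, 0.86 and 0.91 in cat2, cat2 rbohD and cat2 rbohF, that of actin 2.60, 2.56 and 2.47, and that of ubiquitin 1.33, 1.25 and 1.29 (log2, n = 3 each). This GAPDH signal comes from another pair than the 3' GAPDH set at -0.31. The 5' set of the latter was at -0.11 in cat2 rbohF, so that pair went the other way.

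A hypothesis is that the changes in cat2 rbohD are a smaller version of those in cat2 rbohF. After correction for noise, also that of the shared cat2 arrays, the log2 fold changes correlated at 0.906, with a slope of 0.379 of cat2 rbohD on cat2 rbohF. A shift of cat2 as a whole is not removed by this and would raise the correlation too. The correlation was at least 0.639 with any array left out, the lowest value coming without cat2 rbohD replicate 3, where the slope was 0.231. Values without cat2 rbohD replicate 1 or 2 came out at 1.03 and 1.01, above the possible 1, which shows the error of the estimate. These values go with a shared direction across probe sets that may rest in part on 1 array. Single probe sets did not all move less in cat2 rbohD. Adjusted over the 29 called there alone, 11 differed between the double mutants. Of these, 9 lay further from cat2 in cat2 rbohF and the others further in cat2 rbohD. The remaining 18 passed no threshold, which does not show them to be equal. Calling also picks large changes in cat2 rbohD. In cat2 rbohD and cat2 rbohF, CCR2 was at -1.12 and -1.21, PDF1.2 at -1.84 and -1.55, and an unnamed probe set at -2.86 in both. The hypothesis was not otherwise tested gene by gene. The unnamed probe set at -5.15 and -0.64 is part of these values and of the ratio of SDs given above. Which gene it reads is not known here, and it may be RBOHD. Values without this probe set were not computed.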
